A study of Arabidopsis thaliana with 9 samples.

How the data were processed

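The samples were 9 Affymetrix ATH1 arrays of total RNA from above-ground Arabidopsis thaliana tissue, 3 from a HAP5 triple mutant, 3 from a constans mutant and 3 from wild type. The labels state biotin-labelled one-cycle targets. The submitters' processing notes name MAS5 and GCOS with no version. The deposited values are intensity values, the linear MAS5 signal of each probe set, which the authors scaled so that the trimmed mean was 100 on every array. The table held 22810 probe sets and no detection calls. No reads were counted, so there is no sequencing depth, and the number of arrays, 3 per genotype, limits the precision. The labels do not say whether the arrays of a genotype came from separately grown plants, so p-values measure only the spread between these arrays.

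The 64 Affymetrix control probe sets were left out of all tests. Values under the pooled 10th percentile, a signal of 1.029, were set to it, and log2 was taken with no further normalization. A probe set was tested when its mean in at least 1 genotype reached the 40th percentile of all such means, a signal of 18.65, which left 14173 of 22746. Gene names came from the platform annotation given with the data, with the TAIR10.1 gene table used for gene identifiers and gene order only. A single gene was named for 13513 probe sets, several for 503 and none for 8730, and 7691 of the tested probe sets had a single name. The files name no genome build for the probe sets, so no positions are given.

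The 3 genotypes were fitted together in limma 3.58.1 (R 4.3.3) with lmFit and eBayes with an intensity trend, with no covariate and 6 residual degrees of freedom. Tables were read with pandas 2.3.3 in Python 3.11.15. The comparisons were each mutant against wild type and the triple mutant against the constans mutant. P-values were adjusted by Benjamini-Hochberg within a comparison, and an adjusted p under 0.05 was the threshold. Changes shared by both mutants were counted beside 100 simulations in which neither mutant differed from wild type. Gene lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with adjustment over the lists of one kind within a comparison. The list tests were repeated with an estimated correlation and with fry, which tests whether the genes of a list move one way and does not compare them with other genes. No list passed with either.

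The comparisons, tests, named-gene rule and most alternatives were chosen before the data were examined, as were 24 gene lists with 357 genes. Only 43 of these genes had a named probe set, so 3 lists could be tested, 14 had 1 or 2 tested members and 7 had none. For that reason 20 lists of names found in the annotation were added, after the annotation and the control signals of the arrays had been read and before any gene's values. They were corrected after the top-ranked probe sets had been seen, where a symbol named another gene, and before any list's values. The genes named were taken by a rule in each comparison. It gave the 10 with the largest rise and the 10 with the largest fall among called probe sets that matched exactly 1 gene. A further condition was that the genotypes did not overlap. It also gave up to 4 members of each list that passed or had a called member. Not all genes that the rule gave are described below. Unchanged probe sets have a 10% chance that 3 arrays lie apart from 3 others. The 4 mutated genes and FT, SOC1, TSF, FUL, AP1 and FLC were to be named whatever their values, but none had a named probe set in the annotation used. GI, AGL24, SMZ, SNZ, AT5G52660, PYE, BHLH101, JMT, AT5G15950, PRA1.E and the probe sets without a name fall outside the rule and were chosen after their values were seen.

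The method was tested on simulated data of the same size with 200 changed probe sets in 5 runs. Between the triple mutant and wild type it recovered 41.2% of 1.5-fold, 81.8% of 2-fold and 99.1% of 4-fold changes, and 6.5% of its calls were false. With no change simulated between the constans mutant and wild type it called 0.6 probe sets on average. The simulated noise was independent between probe sets, with no structure common to an array. These rates may therefore not hold for the real arrays, where a split that mixed constans and wild-type arrays called 309 probe sets.

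The alternatives were quantile normalization, median centring, no floor, a pseudocount of 6.598, no filter or a filter at the 60th percentile, single-gene probe sets alone, no trend, array weights, a fit of only the 2 genotypes compared, the replicate number as a block, leaving out each array in turn, and a change of at least 2-fold. After the data were seen, the log2 signal of the 25S ribosomal RNA control was tried as a covariate, and the 3 arrays with a 25S signal above 400 were left out together.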

Results

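Transcript levels were measured in Arabidopsis thaliana on Affymetrix ATH1 arrays in 3 genotypes with 3 arrays each, 9 arrays in all. The genotypes were a triple mutant of HAP5 genes, which encode the NF-YC subunits of a CCAAT-binding transcription factor complex, a mutant of CONSTANS, a transcription factor of photoperiodic flowering, and a wild type. All above-ground tissue was collected from plants of 10 days, grown with 16 h of light and 8 h of darkness at 22 °C, at 14 h after lights on. The labels give the wild type as Col-1 and the triple mutant as Col-0, and they give no background for the constans mutant, so genotype and background were not separated. The number of arrays limits the precision of every value here. Each value has n = 3 arrays per genotype, errors of changes are standard errors (SE) from limma, and every adjusted p is a Benjamini-Hochberg value over the 14173 probe sets tested unless stated otherwise.

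The authors' scaling had set the same trimmed mean on all 9 arrays, and their median signals were 33.1 to 37.0. Correlations between arrays ran from 0.952 to 0.985 across probe sets, which are not independent replicates. The control probe set for 25S ribosomal RNA differed far more. Its signal was 42.4, 16.9 and 15.9 in the triple mutant, 56.5, 1152 and 1079 in the constans mutant, and 22.6, 108 and 418 in wild type. The first principal component, with 33.7% of the variance, ran from -21.0, -18.4 and -15.8 for the triple mutant to 4.77, 34.1 and 29.1 for the constans mutant, with wild type at -6.78, -11.4 and 5.41. The HAP5 genes of the triple mutant were taken as NF-YC3, NF-YC4 and NF-YC9 from prior knowledge of the study. The gene names used here covered none of the 4 mutated genes. The transcripts of NF-YC3, NF-YC4, NF-YC9 and CO could therefore not be identified, and neither could those of FT, SOC1, TSF, FUL, AP1 and FLC. Their probe sets may be among the 8730 without a name or the 503 that matched several genes. The calls in each comparison may thus include the mutated genes themselves.

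The triple mutant was compared with wild type to ask which transcripts depended on the HAP5 genes in long days. Cpn60beta3, which encodes a subunit of the plastid chaperonin, fell by 1.31 ± 0.14 (SE) on the log2 scale, from a mean signal of 95.6 in wild type to 38.6 in the triple mutant (2.47-fold lower, adjusted p = 6.92e-04). AT1G47400, which encodes a small peptide of the iron deficiency response, rose by 1.13 ± 0.18, from a signal of 309 to 676 (2.19-fold, adjusted p = 0.0309). AT2G24040 was 2.05-fold lower, the MADS-box gene AGL87 was 1.89-fold lower and AT2G40010, which encodes a ribosomal protein of the P0 family, was 1.74-fold lower, with adjusted p of 0.0124, 0.0404 and 0.0309. In each of these 5 genes the 3 arrays of one genotype all lay beyond the 3 of the other, which was a condition for naming them. Among probe sets without a gene name, 264190_at fell from a signal of 66.5 in wild type to 1.91 in the triple mutant, where 1 of the 3 arrays was at the lowest value allowed, and stood at 63.2 in the constans mutant. Probe set 245712_at rose from 38.8 to 118, or by 1.60 ± 0.16 on the log2 scale. Probe set 264650_at fell from 178 to 60.1, a log2 change of -1.57 ± 0.16.

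Across the array, 13 of 14173 probe sets passed adjusted p under 0.05 between the triple mutant and wild type, 7 higher and 6 lower in the triple mutant. With quantile normalization 3 of 8 were higher, with array weights 73 of 99, and with no filter on dim probe sets 1 of 9, of which 3 were among the 13. Only 5 of the 13 matched a single named gene, 1 higher and 4 lower, 1 matched several genes and 7 had no name. An unadjusted p under 0.05 was met by 923 probe sets. The calls on Cpn60beta3, 245712_at and 264650_at held under every alternative fit that tested them. With no filter on dim probe sets the other 4 named genes and 264190_at did not pass. AT1G47400 and AGL87 did not pass with the 25S signal as a covariate. With no trend, where 4 probe sets passed, the same 4 named genes did not, and neither did AGL87 under quantile normalization, median centring and single-gene probe sets or AT2G40010 under median centring. The call on AT1G47400 ended without triple mutant 1, 2 or 3 or wild type 2 or 3 (adjusted p 0.0563 to 0.166), that on AT2G24040 without triple mutant 2 or 3 or wild type 1 (0.0563 to 0.103), that on AT2G40010 without any triple mutant array or wild type 1 or 2 (0.121 to 0.173), and that on AGL87 without any triple mutant or wild type array (0.117 to 0.215). The count was 5 without triple mutant 2, 7 without triple mutant 3, 5 without wild type 1, 7 without wild type 3, 26 without constans 1, and 27 without the 3 arrays whose 25S signal exceeded 400 (constans 2, constans 3 and wild type 3), the last a setting chosen after the data were seen.

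Genes encoded in the plastid were lower as a group in the triple mutant than in wild type. The median log2 change was -0.32 over 43 plastid-encoded genes of photosynthesis (camera adjusted p = 2.02e-14) and -0.34 over 22 plastid-encoded genes of transcription, translation and other functions (4.49e-09). With an estimated correlation between genes, neither list passed, at adjusted p = 0.828 for both. The median of the photosynthesis list was -0.16 with array weights. No single member of either list passed over all probe sets. The means of psbB, of photosystem II, and rbcL, the large subunit of Rubisco, differed by -0.97 ± 0.22 and -1.19 ± 0.31 on the log2 scale with adjusted p of 0.244 and 0.370, and those of rps14, a plastid ribosomal protein gene, and rpoB, of the plastid RNA polymerase, by -1.78 ± 0.48 (0.370) and -1.73 ± 0.53 (0.507). The 25S ribosomal RNA signal moved with this group in part. All 3 triple mutant arrays stood at 42.4 or below and 2 of the 3 wild-type arrays at 108 and 418. Wild type 1, at 22.6, lay within the range of the triple mutant. Over all 65 plastid probe sets the median change was -0.34, or -0.07 with the 25S signal as a covariate. This covariate was chosen after the data were seen. The 24 nuclear genes of photosynthesis had a median change of 0.06, with no member past the threshold (camera adjusted p = 0.102).

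**Figure D1:**
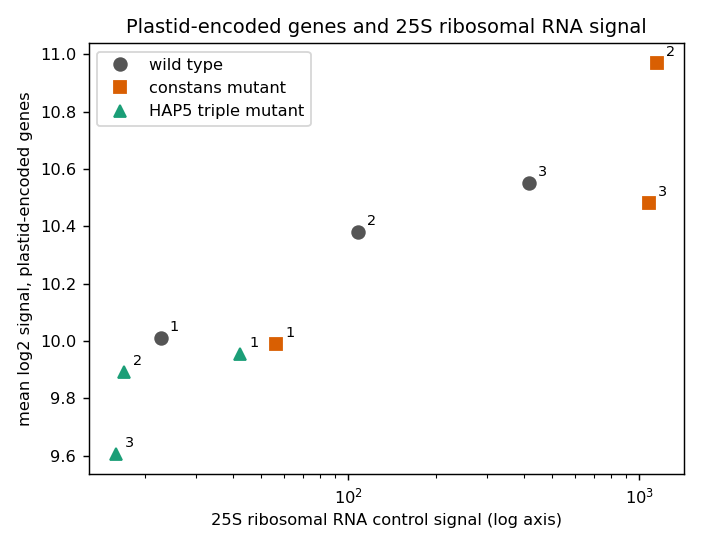
Mean log2 signal of 65 plastid-encoded probe sets (vertical axis) against the signal of the 25S ribosomal RNA control probe set (horizontal log axis) on each of the 9 arrays, with 1 point per array and the replicate number beside it. The triple mutant arrays lie at 9.61 to 9.95 with a 25S signal of 15.9 to 42.4, and constans mutant 2 lies highest, at 10.97 with a 25S signal of 1152.

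Within the genotypes, arrays with more 25S signal had more plastid-encoded signal. The deviations of the 9 arrays from their group means had a Pearson r of 0.876 (exact permutation p = 0.0230, two-sided, over 216 within-group orders) and a Spearman rho of 0.867 (exact permutation p = 0.0280, two-sided). Without the 2 arrays farthest from the median r was 0.654. This was the only relation across arrays that was tested.

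A list of 12 cold and dehydration response genes, written after the gene names had been read, was higher in the triple mutant than in wild type, with a median log2 change of 0.23 (camera adjusted p = 1.81e-05), or 0.36 with the 25S signal as a covariate. Its adjusted p was 0.204 with an estimated correlation. None of its members passed over all probe sets. The dehydration-induced DI21 had a change of 0.85 ± 0.19 (adjusted p = 0.236), the zinc-finger gene STZ 0.58 ± 0.21 (0.634), the cold-regulated COR15A 0.58 ± 0.22 (0.673) and the lipocalin gene TIL 0.37 ± 0.11 (0.429). Of the iron status list, fixed before the data were examined, the transcription factor genes PYE and BHLH101 were the 2 members tested. Their changes of 0.88 ± 0.19 and 0.63 ± 0.35 did not pass over all probe sets (adjusted p = 0.212 and 0.832), and 1 of them passed when adjusted over the list alone. The other 17 lists written after the names had been read did not pass, with adjusted p of 0.102 to 0.983, and neither did the 3 testable lists fixed before, at 0.163 to 0.664.

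The constans mutant was compared with wild type to ask which transcripts depended on CONSTANS. Among the named genes that fell in the constans mutant, AT4G27280, which encodes an EF-hand calcium-binding protein, fell from a signal of 399 to 141 (2.83-fold lower, log2 change -1.50 ± 0.12, adjusted p = 1.32e-05), and AT3G19680 fell by 1.42 ± 0.12, from 454 to 170 (4.26e-05). AT2G20670 fell by 2.51 ± 0.26, from 122 to 21.4 (5.70-fold lower, adjusted p = 1.50e-04). WRKY53, a transcription factor of leaf senescence and defence, fell 2.31-fold (log2 change -1.21 ± 0.18, adjusted p = 2.74e-03). STZ, a zinc-finger repressor of the salt, drought and cold responses, was 2.15-fold lower at a change of -1.11 ± 0.21 (0.0153).

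Among the genes that rose in the constans mutant, AT2G38240, which encodes a jasmonate hydroxylase, rose by 2.82 ± 0.47 on the log2 scale (adjusted p = 6.00e-03), from a dim signal of 10.1 to 71.5, and by 2.11 to 3.22 over the alternative fits. ATPMEPCRB, a pectin methylesterase gene, rose 2.25-fold (1.17 ± 0.16, adjusted p = 1.71e-03), and the receptor-like kinase gene AT1G35710 rose 2.07-fold (1.05 ± 0.17, 5.81e-03). The ubiquitin ligase genes RING1, which promotes cell death in defence, and PUB24, which restrains immune responses, rose by 0.81 ± 0.11 (1.99e-03) and 0.98 ± 0.18 (0.0130). EXLA1, of the expansin-like family, rose by 0.66 ± 0.15 (0.0402). The 10 largest rises among named genes lay between 1.05 and 2.82 and the 10 largest falls between -1.14 and -2.51. The falls also included AT2G41640 (3.26-fold lower), the AP2/ERF transcription factor gene AT1G77640 (3.15-fold), AT1G04770 (2.27-fold), the transporter gene AT5G52050 (2.21-fold), AT5G42200 (log2 change -1.14) and AT4G29780 (-1.27, adjusted p = 0.0403). In each gene called here the 3 arrays of one genotype all lay beyond the 3 of the other. For the 10 largest rises and the 10 largest falls this was a condition for naming them. Of the probe sets without a gene name, 248964_at fell from a signal of 232 to 50.9 in the constans mutant. Probe set 252984_at rose from 2.02, with 2 of the 3 wild-type arrays at the lowest value allowed, to 40.3. Probe set 246525_at fell from a dim 20.7 to 1.89, with 1 of the 3 constans arrays at the lowest value allowed. It stood at 30.3 in the triple mutant. Its call against wild type ended in 1 of the 20 alternative fits that tested it.

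**Figure D2:**
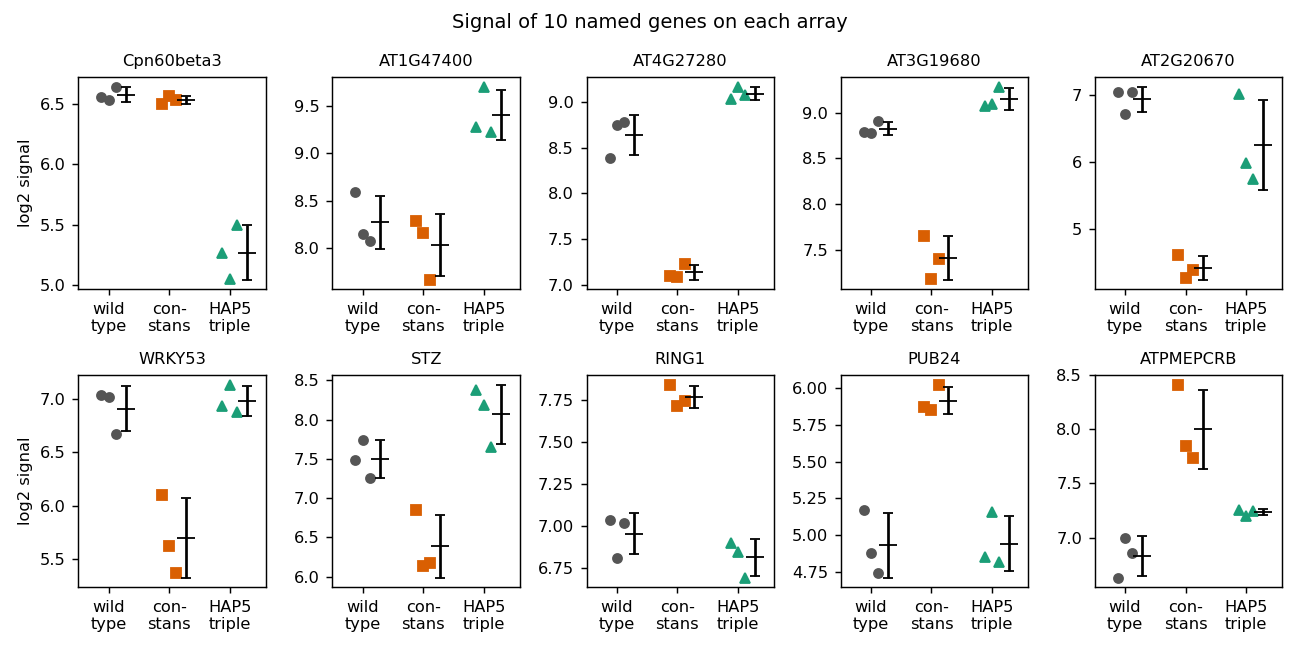
Log2 signal of 10 named genes on each array (1 point per array, 3 arrays per genotype), with the mean and SD of each genotype; the genes were picked after their values were seen. Cpn60beta3 is lower in the triple mutant (mean 5.27) than in wild type (6.58), AT1G47400 is higher there (9.40 against 8.27), and AT4G27280 is lower in the constans mutant (7.14) than in wild type (8.64).

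In all, 198 probe sets passed between the constans mutant and wild type, 111 higher and 87 lower in the constans mutant. With each array centred on its median, 72 of 152 were higher, and with no filter on dim probe sets 23 of 56. A single named gene was matched by 85 of the 198, 48 higher and 37 lower, and 63 of the 198 changed at least 2-fold. The calls on AT4G27280, AT3G19680, AT1G04770, AT5G42200 and 248964_at held under every alternative fit tried. With no filter on dim probe sets AT2G20670, AT5G52050 and RING1 also stayed called, and the other genes named here did not. The call on STZ ended without constans 2 or 3 or wild type 1 or 2 (adjusted p 0.0517 to 0.0888), that on PUB24 without constans 3 or wild type 2 (0.0799 and 0.0612), that on EXLA1 in 6 of the 9 fits that left out an array (0.0643 to 0.159, constans 1, 2 or 3, wild type 1 or 2 or triple mutant 2), that on AT4G29780 in 7 of them (0.0599 to 0.202, all but those without constans 1 or wild type 1), and that on 252984_at without constans 3, wild type 1 or wild type 2 (0.165, 0.0781 and 0.101). With no trend STZ, AT4G29780, EXLA1 and 252984_at did not pass. With only the 2 groups in the fit AT4G29780 and EXLA1 did not, and neither did AT4G29780 with array weights or EXLA1 with median centring and with single-gene probe sets. The count was 98 without constans 3 and 94 without wild type 2. With the 25S signal as a covariate it was 186, of which 144 were among the 198, and STZ, EXLA1 and 252984_at did not pass (0.0504, 0.0818 and 0.0636). It was 56 with no filter on dim probe sets, and 37 without the 3 arrays of high 25S signal, where 1 constans array remained and 34 of the 37 were among the 198. In that last fit ATPMEPCRB stayed called and AT2G20670, AT2G38240, AT2G41640, AT1G77640, AT1G35710, AT5G52050, AT4G29780, WRKY53, STZ, RING1, PUB24, EXLA1 and 252984_at did not pass.

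By group, the 4 tested members of the cold and abscisic acid list, fixed before the data were examined, all had a higher mean in the constans mutant, with a median log2 change of 0.76 (camera adjusted p = 1.63e-03). Its adjusted p was 0.158 with an estimated correlation, and its median was 0.28 without constans 3 and 0.50 with the 25S covariate. None passed over all probe sets, 2 passed adjusted over the list alone, and COR15A came nearest at 0.89 ± 0.22 (adjusted p = 0.0618), followed by COR47 at 0.66 ± 0.23 (0.243). The 3 tested members of the light harvesting list, LHCB4.1, LHCB4.2 and LHCB4.3 of the photosystem II antenna, had a median change of 0.26 (camera adjusted p = 0.0307). With an estimated correlation the adjusted p was 0.158, none passed over all probe sets, and 2 passed adjusted over the list alone. The light harvesting call also ended without constans 2 (adjusted p = 0.131), wild type 1 (0.0647) or wild type 3 (0.0736), under quantile normalization, no trend and array weights, and in both settings with the 25S signal. The 25S signal was 1152 and 1079 in constans 2 and 3 and 418 at most in wild type. Of 13 defence regulators, a list written after the names had been read, RING1 and PUB24 rose, WRKY53 fell and 10 did not pass. Of 12 cold and dehydration response genes, STZ fell and 11 did not pass, while 9 of the 12 had a higher mean. Adjusted over that list alone, 5 rose and 1 fell. Of 17 genes of expansins and xyloglucan modification, EXLA1 rose and 16 did not pass. None of the 20 lists written after the names had been read passed as a list (adjusted p 0.0700 to 0.914).

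Of the flowering genes that could be named, none passed over all probe sets in any comparison. The circadian regulator GI had a change of -1.77 ± 0.61 on the log2 scale between the constans mutant and wild type (adjusted p = 0.245), with an SD of 1.85 among the 3 constans arrays. The floral promoter AGL24 had a change of -0.03 ± 0.23 (0.977), and the floral repressors SMZ and SNZ had -0.43 ± 0.23 (0.524) and -0.39 ± 0.18 (0.438). In the triple mutant against wild type these 4 genes had 0.23 ± 0.61, -0.17 ± 0.23, -0.23 ± 0.23 and -0.11 ± 0.18, with adjusted p of 0.979, 0.950, 0.920 and 0.958. In the triple mutant against the constans mutant they had 2.00 ± 0.61, -0.13 ± 0.23, 0.20 ± 0.23 and 0.28 ± 0.18, with adjusted p of 0.0950, 0.804, 0.690 and 0.436. Adjusted over the 2 tested members of the floral promoter list alone, or of the circadian clock list, GI passed in the constans mutant against wild type and between the mutants, but not in the triple mutant against wild type. The other clock gene, AT5G52660, passed over that list between the mutants (0.48 ± 0.18, adjusted p = 0.184 over all probe sets). Over 9 genes of flowering time and floral meristems the list test gave adjusted p of 0.889 for the triple mutant and 0.134 for the constans mutant against wild type, and 0.580 between the mutants, where 1 of the 9 passed over the list alone.

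The 2 mutants were compared directly to test where they differed. Of the named genes that fell in the constans mutant against wild type, AT4G27280 was 3.88-fold higher in the triple mutant than in the constans mutant (log2 change 1.95 ± 0.12, adjusted p = 5.97e-07), AT3G19680 was 3.35-fold higher (1.75 ± 0.12, 2.86e-06), AT2G41640 was 5.03-fold higher (2.33 ± 0.26, 1.51e-04) and STZ was 3.21-fold higher (1.68 ± 0.21, 3.80e-04). AT4G29780 was 4.86-fold higher and WRKY53 2.43-fold higher, with adjusted p of 3.75e-04 and 8.46e-04. AT1G33760, an AP2/ERF transcription factor gene, had a signal of 25.6 in the triple mutant and 1.4 in the constans mutant, where 2 of the 3 arrays were at the lowest value allowed. On the other side, RING1 was 1.94-fold lower and PUB24 1.96-fold lower in the triple mutant, with adjusted p of 2.32e-04 and 8.10e-03. The xyloglucan-modifying XTH33 was 2.17-fold lower (-1.12 ± 0.23, 0.0155). THI2.2, which encodes the antimicrobial peptide thionin, and the chitinase gene CHI (AT2G43570) were also lower (log2 change -2.78 ± 0.56, 0.0139, and -2.02 ± 0.37, 7.90e-03), at dim signals of 7.05 and 16.4 in the triple mutant. Over the alternative fits their changes ran from -3.30 to -1.82 and from -2.49 to -1.61.

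In all, 479 probe sets passed between the mutants, 274 higher and 205 lower in the triple mutant, 211 of them named genes, and 169 changed at least 2-fold. Of the 198 probe sets called between the constans mutant and wild type, 152 were also called here. Both comparisons use the same constans arrays, and the overlap expected from that alone was not computed. The calls on AT4G27280, AT3G19680, AT2G41640, AT4G29780, STZ and RING1 held under every alternative fit tried. Without constans 3, adjusted p was 0.0506 for PUB24, 0.0518 for CHI and 0.0560 for XTH33, which also stood at 0.0828 without triple mutant 2, and without constans 2 that of THI2.2 was 0.0711. The count was 267, 219 and 281 without triple mutant 1, 2 and 3, and 926, 296 and 208 without constans 1, 2 and 3. Without the 3 arrays of high 25S signal it was 136, of which 116 were among the 479. With the 25S signal as a covariate it was 132, of which 115 were among the 479. With that covariate WRKY53, AT1G33760, PUB24, CHI, XTH33 and THI2.2 did not pass, and all of these except WRKY53 did not pass without the 3 arrays either. With no filter AT1G33760, CHI, XTH33 and THI2.2 did not pass, and the count was 185. THI2.2 did not pass with no trend either.

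Plastid-encoded genes were lower in the triple mutant than in the constans mutant. Of the 43 for photosynthesis 7 fell and 36 did not pass, with a median log2 change of -0.51 (camera adjusted p = 1.83e-13), and of the 22 others 2 fell and 20 did not pass, with a median of -0.49 (2.35e-08). The adjusted p was 0.767 for both with an estimated correlation. Among those that fell were psbB (-1.04 ± 0.22, adjusted p = 0.0184), the cytochrome b6f gene petD (-1.66 ± 0.37, 0.0240), rps14 (-2.07 ± 0.48, 0.0299) and rpl14 (-1.44 ± 0.35, 0.0373). The 25S signal moved with this group, at 15.9 to 42.4 in the triple mutant and 56.5 to 1152 in the constans mutant. Over the 65 plastid probe sets the median was -0.50, and it was 0.02 with the 25S signal as a covariate, where neither list passed (adjusted p = 0.786 for both). Without constans 2 the medians of the lists were -0.28 and -0.27, and both were closer to 0 without the 3 arrays of high 25S signal, where the second, at -0.10, did not pass (adjusted p = 0.230). The 4 genes named here each lost their call in 3 to 6 of the 9 fits that left out an array, psbB without triple mutant 3, constans 2 or constans 3 (0.0805 to 0.0912), petD without triple mutant 2 or 3 or constans 2 or 3 (0.0828 to 0.0908), and rps14 and rpl14 without any triple mutant array or constans 2 or 3 (0.0536 to 0.135), with rpl14 also at 0.0510 without wild type 2. None of the 4 passed with no filter, with no trend, with the 25S covariate or without the 3 arrays of high 25S signal, and rpl14 did not with only the 2 groups in the fit.

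Of the 5 tested genes of glucosinolate metabolism, BCAT4, of methionine chain elongation, and UGT74B1, a glucosyltransferase of the core pathway, rose in the triple mutant against the constans mutant, by 0.58 ± 0.11 (adjusted p = 8.37e-03) and 0.57 ± 0.12 (0.0155). The median was 0.30 (camera adjusted p = 0.0125), or 0.48 without constans 2. The adjusted p was 0.767 with an estimated correlation, and without constans 3 the list stood at 0.0772 with BCAT4 at 0.0518 and UGT74B1 at 0.0547. The list also did not pass without the 3 arrays of high 25S signal (0.185) or with no filter (0.161). BCAT4 also stood at 0.0584 without triple mutant 2, and UGT74B1 at 0.0828 and 0.0561 without triple mutant 2 and 3. With no filter neither passed, with no trend UGT74B1 did not, and in both settings with the 25S signal BCAT4 did not.

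Among the other lists, STZ and TIL rose of 12 cold and dehydration response genes (TIL by 0.43 ± 0.11, adjusted p = 0.0387), WRKY53 rose and RING1 and PUB24 fell of 13 defence regulators, and THI2.2 fell of 11 genes of jasmonate and defensins. NdhN rose and LHCB4.2 fell of 24 nuclear genes of photosynthesis, EXPA16 and EXO rose and XTH33 fell of 17 genes of expansins and xyloglucan modification, and PYK10 fell, the 1 tested member of the root marker list and 1 of 6 root-expressed genes, of which 2 had a higher and 4 a lower mean. Of these calls, that on NdhN ended without any triple mutant array or constans 2 or 3 (adjusted p 0.0541 to 0.0804), as did those on EXO (0.0831 to 0.151) and on LHCB4.2, which ended without wild type 1 too (0.0501 to 0.159). The call on PYK10 ended without triple mutant 2 or 3, constans 2 or 3 or wild type 1 (0.0562 to 0.198), that on EXPA16 without triple mutant 2 or 3 or constans 3 (0.0631 to 0.0786), and that on XTH33 without triple mutant 2 or constans 3 (0.0828 and 0.0560). That on TIL ended in 7 of the 9 fits that left out an array, all but those without constans 1 or wild type 3 (0.0543 to 0.153). NdhN, EXO, LHCB4.2, PYK10, EXPA16, XTH33 and TIL also did not pass with no filter or in either setting with the 25S signal, and all of these except EXPA16 and XTH33 did not with no trend. Further losses were those of EXO, LHCB4.2 and PYK10 with median centring, EXO, PYK10 and TIL with only the 2 groups, EXO and TIL with single-gene probe sets and TIL with quantile normalization. The other 17 lists written after the names had been read did not pass (0.580 to 0.904), and neither did the 3 testable lists fixed before (0.213 to 0.221).

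The overlap of both mutants' changes against wild type addressed whether the HAP5 genes and CONSTANS affected the same transcripts. Called in both and in the same direction were 2 probe sets. One was 245712_at, which rose by 1.60 in the triple mutant and 1.44 in the constans mutant, and the other matched 2 genes. The count was 1 in each fit that left out an array other than triple mutant 3 or constans 1. In 100 simulations of unchanged mutants that shared the wild-type arrays, the mean was 0.03 and the highest 1. Unchanged mutants give few calls, so a low count there was fixed in advance. It cannot say whether 2 exceeds what lists of 13 and 198 calls would share. Independent lists of these sizes would share 0.092 in the same direction, a value that ignores the shared wild-type arrays. Probe set 248964_at went opposite ways, with 0.96 in the triple mutant and -2.19 in the constans mutant, and differed between the mutants at an adjusted p of 6.99e-09. Across probe sets, which are not independent replicates, the changes of both mutants had a correlation of 0.0928. The simulations gave 0.478 to 0.517, with noise independent between probe sets and of the same spread on every array. The real arrays held common structure, and a change in 1 mutant alone also lowers the correlation. That range therefore cannot say whether the mutants differed more than shared wild-type arrays allow. The correlation was -0.0233 without constans 1, 0.240 without wild type 3 and 0.366 with no filter on dim probe sets.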

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

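The tests chosen only after their results were seen were the counts over other splits of the arrays, the change of the nuclear genes of photosynthesis, both counts with the 25S covariate and the choice to compare control signals with wild type; the correlation of plastid-encoded and 25S signals was chosen before its value was seen.

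Control probe sets outside the comparisons stood above their highest wild-type level in the constans mutant. The 25S ribosomal RNA signal was 1152 in constans 2 and 1079 in constans 3, against 418 at most in wild type. The 5S ribosomal RNA signal was 360.2 in constans 2, against 212 at most in wild type.

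The first pattern is the lower plastid-encoded signal in the triple mutant, at a median log2 change of -0.34 against wild type. Less photosynthetic tissue or fewer plastids per shoot might also lower nuclear genes of photosynthesis, a premise that was not tested. The median of these genes was 0.0611 (95% bootstrap interval 0.0188 to 0.113 over 24 genes), above -0.168, which is 50% of the plastid median. That interval holds the spread between genes on the same arrays and not the spread between arrays, so it does not settle this explanation. The amount of non-polyadenylated RNA labelled on each array, for which the 25S signal stands, may account for much of the pattern, since plastid-encoded and 25S signals went together within the genotypes (r = 0.876, exact permutation p = 0.0230, 9 arrays). With the 25S covariate the median was -0.07, while without the 3 arrays of high 25S signal that of the photosynthesis genes was -0.25. A lower level of plastid transcripts in the triple mutant stays open and untested.

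The second pattern is the set of 198 probe sets called between the constans mutant and wild type. They were picked on these same arrays for a large change against a small spread within genotypes. The slope of the 25S covariate rests on deviations within genotypes, so changes picked in this way tend to keep their size. Their size with the covariate therefore cannot decide whether labelled non-polyadenylated RNA was their whole cause. The median absolute log2 change went from 0.864 (SE 0.151) to 0.901 (SE 0.162). In the same fit 100% of them kept their direction at an unadjusted p under 0.05. That threshold is looser than the one that picked them from the same arrays, so this share decides little. In that fit 144 of the 198 passed the adjusted threshold and 54 did not, and in these the median absolute log2 change went from 0.723 (SE 0.159) to 0.705 (SE 0.172), with a wider error in 50 and a smaller change in 37. The real split called 198, and of the 10 splits of the 6 arrays into 3 and 3, too few for a share under 0.05, 2 gave as many, the other calling 309. That split parted constans 2, constans 3 and wild type 3, the arrays of the highest 25S signal, from the rest, which points to a structure of the arrays beside genotype, and the genotype itself stays open as untested.

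The third pattern is the set of 479 probe sets called between the mutants. With the 25S covariate all 479 kept the direction, and the median absolute log2 change went from 0.827 (SE 0.157) to 0.720 (SE 0.217). These probe sets were picked on the same arrays. The 25S signals of the mutants did not overlap, at 42.4 or below in the triple mutant and 56.5 or above in the constans mutant. That size therefore cannot decide whether labelled RNA was the whole cause. An unadjusted p under 0.05 in the same direction was kept by 82.3% of them (394 of 479). That threshold is looser than the one that picked them from the same arrays, so this share decides little. In that fit 132 probe sets passed the adjusted threshold. Of the 479, 364 did not pass there, and in these the median change went from 0.730 (SE 0.157) to 0.620 (SE 0.218), with a wider error in 352 and a smaller change in 270. Part of the set may still follow the 25S signal; of 10 splits, too few for a share under 0.05, the real one called 479 and the highest other 0.

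For the triple mutant against wild type, the real split called 13 probe sets and the highest of the other splits 2; as many as the real one were called by 1 of the 10 splits, the real one itself, too few splits for a share under 0.05.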

How the results depend on the processing

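The settings with the 25S signal, as a covariate and without the 3 arrays of high 25S signal, were chosen only after the data were seen, and the others before. The counts of 13 (triple mutant against wild type), 198 (constans mutant against wild type) and 479 (between the mutants) stayed within 1.5 times under a pseudocount and the stricter filter. With no floor the same probe sets were called as in the main fit. In the same order, the moved counts were 8 for the first under quantile normalization and 8 under median centring, 56 and 185 for the last 2 with no filter, where the first was 9 with only 3 of the 13 among them, 4, 73 and 176 with single-gene probe sets, 4, 102 and 306 with no trend, 99 and 1192 for the first and last with array weights, 28 for the first with only the 2 groups in the fit, and 8, 63 and 169 with a 2-fold limit. Fewer probe sets were tested with single-gene probe sets and a limit was added with 2-fold; for the other settings the cause was not tested. With the replicate block the first count was 20, the others 234 and 661, though the replicate numbers did not pair the arrays: deviations of arrays with the same number correlated at -0.0384 to 0.227, over 0.1 in 3 of 9 pairs. With the 25S covariate the counts were 8, 186 and 132, and without the 3 arrays of high 25S signal 27, 37 and 136, with 1 constans array, assumed to vary like the other groups. Leaving out each array in turn gave 5 to 26, 94 to 225 and 208 to 926.

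The 2 shared changes became 1 under quantile normalization, median centring, no trend, the 25S covariate and without the 3 arrays of high 25S signal, 0 with single-gene probe sets, which leave out both, 4 with no filter and 8 with array weights, and ranged from 1 to 2 without each array. The correlation of both mutants' changes, 0.0928, ranged without each array from -0.0233 without constans 1, where it reversed, to 0.240 without wild type 3, and over the other settings from 0.0248 with the stricter filter to 0.366 with no filter. Of the lists fixed before, 2 passed, 1 under quantile normalization and no trend, and 1 to 3 without each array. Of the added lists 6 passed over the 3 comparisons, 11 with array weights, and 6 to 10 without each array. With an estimated correlation and with fry, 0 lists fixed before and 0 added lists passed. The median of the plastid-encoded gene expression list between the mutants reversed to 0.0360 with the 25S covariate; that this covariate overlaps with the genotypes was not separated from other causes, and the cause was not tested.

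Of the 77 calls on named genes and unnamed probe sets in the table of named items, none reversed in any of the 22 settings that refit the data. Still called were 24 with no filter, 49 with no trend and 37 with the 25S covariate of 77, and 28 of 76 without the 3 arrays of high 25S signal. The alternatives for the mutated genes were not run, since none of the 4 had a named probe set. Dim probe sets limit the fold changes. Among the probe sets described here, 264190_at, 252984_at, 246525_at and AT1G33760 had arrays at the lowest signal of 1.029, so their fold depends on it. Where a mean lay under the filter's 18.65, as for AT2G38240, THI2.2, CHI, AT2G24160 and AT2G34140, the fold is imprecise. Other named items, not described here, were as dim.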

Other observations

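Both tests of gene neighbourhoods in this part, and the window of 25 genes, were chosen only after AT5G15950 had been seen near CO among the called genes.

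Beside the lists, the direct comparison of the mutants held genes that no list covered. AT2G24160 was 3.03-fold lower in the triple mutant than in the constans mutant (-1.60 ± 0.30, adjusted p = 8.93e-03), and AT2G34140 was 2.90-fold lower (-1.54 ± 0.28, 7.05e-03; 0.0518 without constans 3). Neither passed with no filter, with the 25S covariate or without the 3 arrays of high 25S signal. The iron genes PYE and BHLH101 had changes of 0.63 ± 0.19 and 1.17 ± 0.35 in that comparison, with adjusted p of 0.0910 and 0.0909, and both passed adjusted over the list of 2 alone. JMT, which encodes jasmonic acid methyltransferase, had -0.81 ± 0.21 in the triple mutant (adjusted p = 0.362) and -0.82 ± 0.21 in the constans mutant (0.0734) against wild type.

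One hypothesis was that DNA linked to an insertion, or an effect of the insertion on its neighbours, may change genes near the mutated loci (gene order from TAIR10.1). Within 25 genes on either side of CO, 1 of 19 tested named genes, AT5G15950, was called between the constans mutant and wild type (5.26%, against 1.08% of the others; Fisher's exact test, one-sided p = 0.189, upper 95% bound 26.0%). Near NF-YC3, NF-YC4 and NF-YC9, 1 of 41 tested named genes, PRA1.E, had an unadjusted p under 0.01 between the triple mutant and wild type (2.44%, against 1.34%; Fisher's exact test, one-sided p = 0.427, upper 95% bound 12.9%). With so few tested genes near the loci, such an effect can be neither shown nor excluded.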
